A study of Mus musculus with 6 samples.

How the data were processed

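RNA from cells labelled as mouse ESCs was measured in 6 samples. Per the labels' protocols, 500 ng of total RNA was poly(A)-selected and made into libraries with the TruSeq Stranded mRNA kit and 8 PCR cycles. The submitters' processing notes list cutadapt 1.6, STAR 2.5.0a, HTSeq 0.5.3, DESeq 1.22.1 and the mouse build mm10, without settings. The deposited values are a signal without an upper bound: per the submitters' processing notes and the file header, read counts per gene scaled by DESeq. Whether HTSeq used the strand of the reads is not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies such as histones, ribosomal proteins and the Gsta, Rhox and H2 families, are uncertain.

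The scale was checked on the values. Within a sample, 100.0% of values were whole multiples of a single step within 0.001 read, and median-ratio size factors of the whole numbers gave back the steps, so whole reads were recovered. The lowest sum over the 6 samples was 15 reads, so the table holds no gene below that. Of 17912 genes, 17860 (99.71%) matched GENCODE M21 (GRCm38, the same assembly as mm10) by identifier without version, which gave positions, 3′ UTRs for 15106 genes and Entrez identifiers for 15220. The chi-square per degree of freedom was 12.18 to 15.65 between clones and 36.3 to 62.13 between controls, above counting noise, which does not tell separate cultures from separate preparations. Each library was treated as a replicate on the basis of its title.

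Groups came from the sample titles. Control replicates are numbered 1 to 3 and clones 5 to 7, so no numbers pair the groups. The main test was limma 3.58.1 (lmFit, then eBayes with trend) on log2(value + 1) for genes with a mean of at least 10 over the 6 samples, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. Where a group had no read, the fold is a bound against a floor of 3 reads per library, and where a group had 1 to 3 reads, the ratio of means is given with an exact 95% Poisson interval of those reads. Exosc2 was also tested with an exact two-sided permutation test.

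A total of 32 gene lists fixed before the data were examined, with 1045 members of which 976 were in the table, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 31 lists that had at least 3 tested members. Exosc6, a member of the exosome list, is not analysed here. Reactome sets shipped with fgsea 1.28.0, with 15 to 300 tested members, were handled likewise. Genes whose longest annotated 3′ UTR holds an AU-rich motif were compared with other genes that have a 3′ UTR. The rule for named genes, also fixed beforehand, took Exosc2, the other exosome subunits, the 10 largest rises and 10 largest falls among called genes with a mean of at least 50 and no overlap between groups, and the 3 members of each list with the smallest p. Genes outside this rule are said to be so where they are named. Not every gene the rule takes is described in the text.

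Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, TMM and quantile scaling, eBayes without trend and with robust estimation, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, chromosome centring (subtracting in each library the median deviation of each chromosome from the control mean), and leaving out each sample. With edgeR and DESeq2, gene lists and sets were tested with cameraPR, the form of camera that takes gene statistics, at the preset correlation. The main test was also run on simulated counts with 200 genes changed by known folds. These counts were drawn from the control means, the library sizes and the trended dispersion of this comparison. Among 15247 genes tested there, limma recovered 71.2% of genes changed 2-fold, 96.9% of those changed 4-fold and 15.2% of those changed 1.5-fold, and called 1 of 15050 unchanged genes. Far fewer genes changed there than were called in the real comparison, which makes the adjustment stricter. These rates therefore do not carry over to it. Analyses used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.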

Results

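Poly(A) RNA was sequenced in 6 libraries labelled as mouse embryonic stem cells (ESCs), pluripotent cells taken from the early embryo. The labels give 3 as wild-type controls (replicates 1, 2 and 3) and 3 as clones carrying a short hairpin RNA against Exosc2 (replicates 5, 6 and 7). In the clones 31 of 33 tested pluripotency genes were lower (given further on), so the ESC label may not describe their state. EXOSC2 is a subunit of the RNA exosome, the complex that degrades and trims RNA from the 3′ end. The series title places the work in the context of EXOSC2 dysregulation in aging and cancer, and its design text compares ESCs with their knockdown derivatives. The table held scaled read counts for 17912 genes. Recovered reads numbered 24633836, 21107761 and 22201525 in control replicates 1, 2 and 3, and 24533508, 24268430 and 26494985 in clones 5, 6 and 7. Whether the controls carried a control hairpin or none, and whether they and the clones share a parental ESC line, is not given in the sample labels, so differences between the groups are not tied to Exosc2 alone. The labels also do not say whether the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All levels below are scaled counts, given as mean ± SD with n = 3 libraries per group, and log2 fold changes are knockdown over control on the log2(scaled count + 1) scale, with their SE.

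Exosc2 was lower in all 3 clones than in all 3 controls. The gene (ENSMUSG00000039356.15, chromosome 2, positions 31670715 to 31681349 in GRCm38) measured 2457, 2473 and 1954 in control replicates 1, 2 and 3, and 1138, 997 and 981 in clones 5, 6 and 7. The group means were 2295 ± 296 and 1038 ± 86.6, so the clones retained 45.3% of the control level. The log2 fold change was -1.14 ± 0.13, with an adjusted p of 5.1e-05 in limma. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. Of the 15179 genes tested, 3597 (23.7%) had a lower log2 fold change than Exosc2.

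Other genes of the exosome list also changed. This list holds subunits and the associated factors Mphosph6 and C1d. Of 12 tested, 7 fell, 2 rose and 3 did not pass the test, with a median log2 fold change of -0.53. The catalytic subunit Dis3 fell from 6114 ± 686 to 1317 ± 112 (log2 fold change -2.21 ± 0.12). The associated factor Mphosph6 fell by 1.55 on the log2 scale (SE 0.16). The ring subunits Exosc7, Exosc8 and Exosc9 had log2 fold changes of -1.03, -1.02 and -0.92. C1d, a nuclear cofactor of the complex, rose from 750 ± 67.1 to 1264 ± 71.9. Exosc3 and Exosc4 passed with log2 fold changes of -0.60 and 0.74, but each call was lost when some single libraries were left out. Without control replicate 1, control replicate 2 or clone 7, Exosc3 had log2 fold changes of -0.48, -0.49 and -0.57. Without control replicate 1, control replicate 3, clone 6 or clone 7, Exosc4 had 0.71, 0.44, 0.64 and 0.69. The Exosc4 call was also lost with TMM, with quantile normalization, with eBayes without trend and with edgeR. As a set the 12 were not called (camera adjusted p = 0.220, and adjusted p = 0.679 with an estimated correlation). Dis3 lies on chromosome 14 and Mphosph6 on chromosome 8, whose genes were lower in the clones as a whole (chromosome medians are given further on). With chromosome medians subtracted, 5 of the 12 fell and 1 rose, with a median of -0.26. Exosc3, Exosc4 and Exosc10 then no longer passed.

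**Figure D1:**
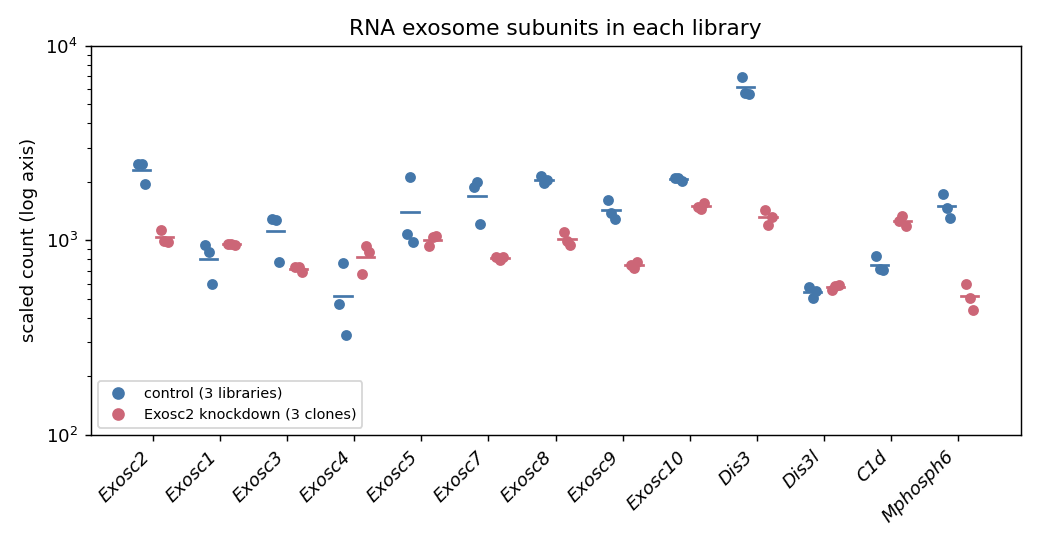
Scaled counts (log axis) of Exosc2 and 12 other genes of the RNA exosome list, the associated factors Mphosph6 and C1d included. Points stand for libraries and horizontal lines for group means. The Exosc2 values of the 3 clones lie between 981 and 1138, below the lowest control at 1954, and Dis3 shows the largest fall among the subunits plotted.

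The transcriptome of the clones differed widely from that of the controls. At an adjusted p under 0.05, 11158 of 15179 genes changed, 5347 higher and 5811 lower in the clones. A change of at least 2-fold was seen for 7300 genes, 3395 higher and 3905 lower. The 3 control and 3 knockdown values did not overlap for 11728 genes (77.3%), where chance gives 10%. Across genes, log2 values correlated between clones at Pearson r from 0.990 to 0.992, between controls at 0.975 to 0.986, and between a clone and a control at 0.792 to 0.803. Genes are not independent replicates, so these are descriptions of the libraries. Whole reads recovered from the table gave 11150 changed genes with edgeR and 11132 with DESeq2.

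The genes with the 10 largest falls had few or no reads in the clones. Tdgf1, a Nodal co-receptor, fell from 24959 ± 1913 to 1.94 ± 0.892. Esrrb, an orphan nuclear receptor of naive pluripotency, fell from 16546 ± 736 to 2.27 ± 0.432. Nanog, a core pluripotency factor (chromosome 6, start 122707489), had 28918 reads in the controls and 2 in the clones, a ratio of 14387 with a 95% counting interval of 3983 to 118801. The RNA-binding protein gene Lin28a had 3 reads in the clones, a ratio of 7587 (interval 2596 to 36789). Lefty2, a Nodal antagonist, and Trh, the thyrotropin-releasing hormone precursor, also had 3 reads each, with ratios of 11279 (3859 to 54691) and 6945 (2377 to 33679). Zfp42, Utf1 and Triml2 had no read in any clone. Against a floor of 3 reads per library they were at least 2133-fold, 1036-fold and 816-fold lower. Bex1 completed the 10, with 6323 ± 1051 in controls and 1.64 ± 1.16 in the clones. Intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

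The genes with the largest rises had low or no counts in the controls. Ehf, an epithelial transcription factor (chromosome 2, start 103263433), rose from 1.69 ± 0.605 to 16997 ± 810. Srgn, which encodes the proteoglycan serglycin, rose from 5.33 ± 2.28 to 27580 ± 1833. Tph1, an enzyme of serotonin synthesis, reached 42780 ± 2464 from 12.8 ± 6.76. Aspa, Avil and Alox8 measured 13006 ± 453, 17786 ± 1062 and 14738 ± 1093 in the clones, against control means of 1.95, 6.48 and 5.34. The keratin gene Krt6a, Tmigd1 and the protease inhibitor gene Serpinb3a had no control read, and were at least 1206-fold, 964-fold and 772-fold higher. Krt6a and Serpinb3a have close paralogs, so how reads were divided among copies is uncertain.

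Pluripotency genes fell together, with marked exceptions. Of 33 list members tested, 31 fell, 2 rose and none failed the test, and the median log2 fold change was -5.53. The list was called lower (camera adjusted p = 2.6e-10), but adjusted p = 0.363 with an estimated correlation. Dppa5a fell from 13193 ± 1597 to 38.1 ± 3.69. The members that rose were Pou5f1 and Klf4, chosen here after their values were seen, as were Sox2 and Myc. Pou5f1, which encodes OCT4, rose from 21045 ± 4721 to 91114 ± 2227 (log2 fold change 2.14 ± 0.16, adjusted p = 3.7e-06 in limma). Klf4 rose from 2415 ± 82.0 to 14169 ± 2032 (2.54 ± 0.12). Sox2 fell from 11834 ± 2168 to 2805 ± 787 (-2.10 ± 0.21). Myc, which stands in the list of short-lived AU-rich transcripts, rose from 265 ± 85.0 to 11859 ± 874 (5.54 ± 0.23), while its paralog Mycn fell from 3064 ± 1228 to 8.82 ± 1.69. Pou5f1 has processed pseudogenes, so part of its count is uncertain.

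**Figure D2:**
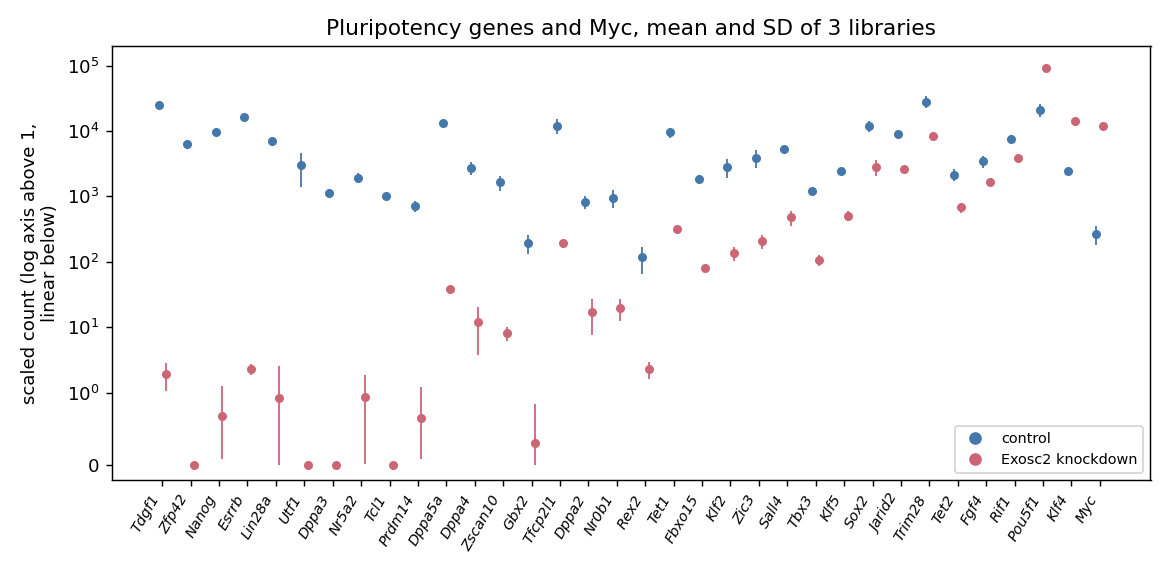
Mean and SD over 3 libraries of the scaled counts of 33 pluripotency genes and Myc (log axis above 1, linear below), for controls and Exosc2 knockdown clones. Tdgf1, Zfp42, Nanog and Esrrb lie below 3 in the clones, while Pou5f1, Klf4 and Myc lie above their control means.

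Germline genes held silent by DNA methylation in somatic cells were mostly lower. Of 32 tested, 30 fell and 2 rose, with a median log2 fold change of -6.85, or -5.76 with members at no read set to their bound. Rhox5 fell from 1570 ± 244 to 17.5 ± 3.22. Tex19.1 had 2999 reads in the controls and 1 in the clones, a ratio of 3271 (95% counting interval 587 to 129199), and Mageb16 was at least 102-fold lower. The camera adjusted p was 1.0e-09, and adjusted p = 0.404 with an estimated correlation. Genes of the formative and primed state fell in 16 of 20 cases and rose in 2 (median -4.51, or -3.47 with bounds, -2.87 with a pseudocount of 5 and -2.93 with a mean of at least 50, camera adjusted p = 5.0e-04, adjusted p = 0.536 with an estimated correlation). Otx2 and Pou3f1 were at least 273-fold and 110-fold lower, and the methyltransferase gene Dnmt3b fell from 2997 ± 770 to 65.3 ± 5.48. Mesendoderm genes fell in 13 of 20 cases and rose in 5 (median -3.22, or -3.19 with bounds, camera adjusted p = 0.0377, adjusted p = 0.536 with an estimated correlation). T had 657 reads in the controls and none in the clones, Nodal fell from 1020 ± 261 to 1.32 ± 0.634, and Twist1 rose from 68.2 ± 5.55 to 1029 ± 201. The mesendoderm call was lost with a mean of at least 50 (median -1.98), with quantile normalization and with DESeq2.

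Markers of other lineages moved in both directions, and these lists were not called. Neuroectoderm genes rose in 7 and fell in 9 of 18 cases (median -0.29, camera adjusted p = 0.528, median 0.04 after chromosome centring, -0.02 with quantile normalization and 0.53 with a mean of at least 50), with Olig2 and Elavl3 at least 126-fold and 192-fold lower. Trophoblast genes rose in 6 and fell in 10 of 18 (median -1.64, adjusted p = 0.524). Among these, Tfap2a rose from 25.6 ± 4.22 to 1097 ± 142, Cdx2 was at least 39.6-fold lower, and Peg10 fell from 10096 ± 8139 to 54.6 ± 12.2. Primitive and visceral endoderm genes rose in 6 and fell in 8 of 20 (median -0.39, adjusted p = 0.582, median -0.91 without a filter, -0.12 with quantile normalization and above 0 with a mean of at least 50), with Apoe falling from 13212 ± 5061 to 9.16 ± 4.77 and Lama1 from 518 ± 128 to 1.95 ± 0.983. Blood and endothelial genes rose in 2 and fell in 5 of 11 (median -0.68, 0.20 with quantile normalization and 0.21 with a mean of at least 50, adjusted p = 0.555). Runx1 rose from 71.1 ± 9.53 to 2551 ± 141 and Pecam1 fell from 1875 ± 176 to 11.1 ± 2.20. Only Sp110 and Zfp750 of the two-cell-like list were in the table, too few for a set test, and both rose, by log2 fold changes of 3.37 and 1.61.

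Fibroblast and feeder-cell markers were mostly higher in the clones. Of 29 tested, 23 rose, 2 fell and 4 did not pass, with a median log2 fold change of 1.53 (camera adjusted p = 4.3e-04, adjusted p = 0.679 with an estimated correlation). Vim rose from 4053 ± 387 to 27647 ± 2113, Col3a1 from 352 ± 98.5 to 4121 ± 716 and Col6a2 from 153 ± 11.7 to 965 ± 92.4. The members that fell were Fn1, from 47207 to 22285, and Thy1, from 394 to 209, chosen, like Dcn, after their values were seen. Dcn, which encodes the fibroblast matrix protein decorin, measured 8.83 in controls and 28.0 in the clones. Y-linked genes were low in both groups: 1 of 4 rose and none fell (median 0.18, camera adjusted p = 0.737), while 3 of 4 rose with a median of 1.10 under quantile normalization. Kdm5d measured 10.5 ± 5.41 in controls and 35.7 ± 14.3 in the clones, Eif2s3y 86.1 ± 17.4 and 54.1 ± 22.1, and Ddx3y had a log2 fold change of 0.27 ± 0.34.

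The interferon, NRF2, p53 and unfolded protein response lists were called higher at the preset correlation. Interferon and double-stranded RNA response genes rose in 27 of 41 cases and none fell (median 1.32, camera adjusted p = 2.1e-04, adjusted p = 0.679 with an estimated correlation). Xaf1 rose from 191 ± 57.8 to 4064 ± 419, Rnf213 from 3972 ± 737 to 15927 ± 2009, and the MHC class I gene H2-D1 from 982 ± 32.5 to 3679 ± 345. NRF2 targets and antioxidant enzymes rose in 17 and fell in 4 of 30 cases (median 0.63, adjusted p = 0.0117, adjusted p = 0.679 with an estimated correlation), with Nqo1 at 936 ± 81.0 and 6845 ± 208. p53 targets rose in 20 and fell in 7 of 35 cases (median 0.68, adjusted p = 0.0184, adjusted p = 0.679 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose from 2346 ± 126 to 15731 ± 753 and Plk2 from 826 ± 225 to 10657 ± 890, while the proapoptotic Pmaip1 fell from 2552 ± 506 to 478 ± 6.73. The p53 call was lost with a mean of at least 50, with quantile normalization and with edgeR. Unfolded protein response genes rose in 15 of 24 cases and fell in 1 (median 0.54, adjusted p = 0.0117, adjusted p = 0.536 with an estimated correlation), with Xbp1 up from 1001 ± 74.3 to 3028 ± 58.4, Dnajb11 up by 1.51 on the log2 scale and Derl3 down from 136 ± 36.2 to 2.94 ± 0.161. That call was lost with quantile normalization, edgeR and DESeq2.

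Genes of cyclin-dependent kinase inhibition and senescence rose in 14 and fell in 5 of 20 cases (median 1.08, camera adjusted p = 0.0406, adjusted p = 0.624 with an estimated correlation). Igfbp3, a secreted binder of insulin-like growth factors, rose from 860 ± 214 to 119053 ± 7274, and Lmnb1 fell from 8386 ± 840 to 1501 ± 69.5. The call was lost without control replicate 1 (median 1.11) or control replicate 2 (median 1.08), and with a mean of at least 50, with quantile normalization and with chromosome centring. Integrated stress response genes moved both ways, 10 higher and 19 lower of 35 (median -0.37, -0.24 after chromosome centring, adjusted p = 0.528), with the cystine transporter gene Slc7a11 rising from 38.4 ± 10.1 to 18305 ± 2352 and Slc7a3 from 1867 ± 224 to 17110 ± 507 and Cth by 3.24 on the log2 scale. Glutathione metabolism genes also moved both ways, 14 higher and 15 lower of 35. Their median was -0.13, 0.00 after chromosome centring and -0.24 with quantile normalization, while their mean was 0.24 and the test pointed upward without a call (adjusted p = 0.555). Besides Slc7a11, Gss, which makes glutathione, rose from 573 ± 31.2 to 6604 ± 298 and Gsta3 from 53.9 ± 13.4 to 3201 ± 144.

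The cell cycle, DNA damage, cholesterol synthesis and ribosome lists were called lower at the preset correlation. Cell cycle genes fell in 35 and rose in 4 of 46 cases (median -0.75, camera adjusted p = 1.5e-04, adjusted p = 0.536 with an estimated correlation). The replication helicase genes Mcm3 and Mcm6 fell from 19108 ± 1049 to 3941 ± 190 and from 20546 ± 2140 to 6015 ± 330, and the checkpoint gene Bub1b fell by 1.75. DNA damage signalling and homologous recombination genes fell in 23 of 30 cases and none rose (median -1.02, adjusted p = 1.1e-04, adjusted p = 0.536 with an estimated correlation), with Blm, Rad51c and Bard1 at log2 fold changes of -3.42, -2.60 and -2.06. Cholesterol synthesis genes fell in 20 and rose in 1 of 24 cases (median -1.68, adjusted p = 1.1e-04, adjusted p = 0.404 with an estimated correlation), with Hmgcs1 falling from 6824 ± 685 to 1076 ± 42.1 and Dhcr7 from 2045 ± 160 to 206 ± 21.1.

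Cytosolic ribosomal protein genes fell in 46 of 79 cases and none rose (median -0.41, camera adjusted p = 6.9e-04, adjusted p = 0.679 with an estimated correlation). Ribosome biogenesis genes fell in 39 and rose in 3 of 60 cases (median -0.49, adjusted p = 0.00106, adjusted p = 0.679 with an estimated correlation). The leading members Rps24, Rpl15 and Gnl3 lie on chromosome 14 and Rpl7, Wdr12 and Ddx18 on chromosome 1, whose genes were lower in the clones as a whole. With chromosome medians subtracted, the medians were -0.35 and -0.56, with 43 and 37 members falling, and Polr1a and Nifk were among members that changed sign. Respiratory chain genes fell in 27 and rose in 4 of 48 cases without a call (median -0.43, adjusted p = 0.0690), and Ndufb3 was among members that changed sign with chromosome medians subtracted. Glycolysis genes rose in 14 and fell in 9 of 30 cases (median 0.04, mean -0.16, test upward with adjusted p = 0.528, median 0.09 after chromosome centring and -0.10 with quantile normalization). The glucose transporter gene Slc2a3 fell from 50295 ± 15217 to 30.7 ± 9.83 and Ldhb from 6182 ± 659 to 153 ± 18.4.

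RNA decay genes and their targets were examined because the exosome takes part in decay of AU-rich mRNAs. Exosome cofactor genes rose in 3 and fell in 5 of 12 cases (median -0.01, 0.02 after chromosome centring and -0.21 with quantile normalization, camera adjusted p = 0.737), with Skiv2l2, Pabpn1 and Wdr61 at log2 fold changes of -0.95, -1.07 and -0.91. Decay and AU-rich-element-binding factor genes rose in 5 and fell in 17 of 31 cases (median -0.34, adjusted p = 0.188), with a median of -0.18 after chromosome centring and, where the list was called, -0.53 with quantile normalization. The deadenylase genes Cnot6 and Cnot6l rose by 2.04 and 1.80 on the log2 scale and Hnrnpd fell from 12945 ± 1961 to 4235 ± 330, while Elavl1, Lsm1 and Cnot7 changed sign with chromosome medians subtracted. Short-lived AU-rich transcripts rose in 23 and fell in 12 of 43 cases (median 0.61, adjusted p = 0.103). Fosl1 rose from 114 ± 13.7 to 2010 ± 224, and Pim1 fell from 4682 ± 584 to 434 ± 26.0. Genes whose longest annotated 3′ UTR holds TTATTTATT numbered 1102, with a median log2 fold change of 0.17, against -0.07 for 12612 genes without it. The difference was not called (adjusted p = 0.203 in limma's camera, a single test). Within quartiles of 3′ UTR length the p-values were 0.0188, 0.471, 0.434 and 0.887 from shortest to longest, and the smallest became 0.0754 after Benjamini-Hochberg adjustment over the quartiles.

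**Figure D3:**
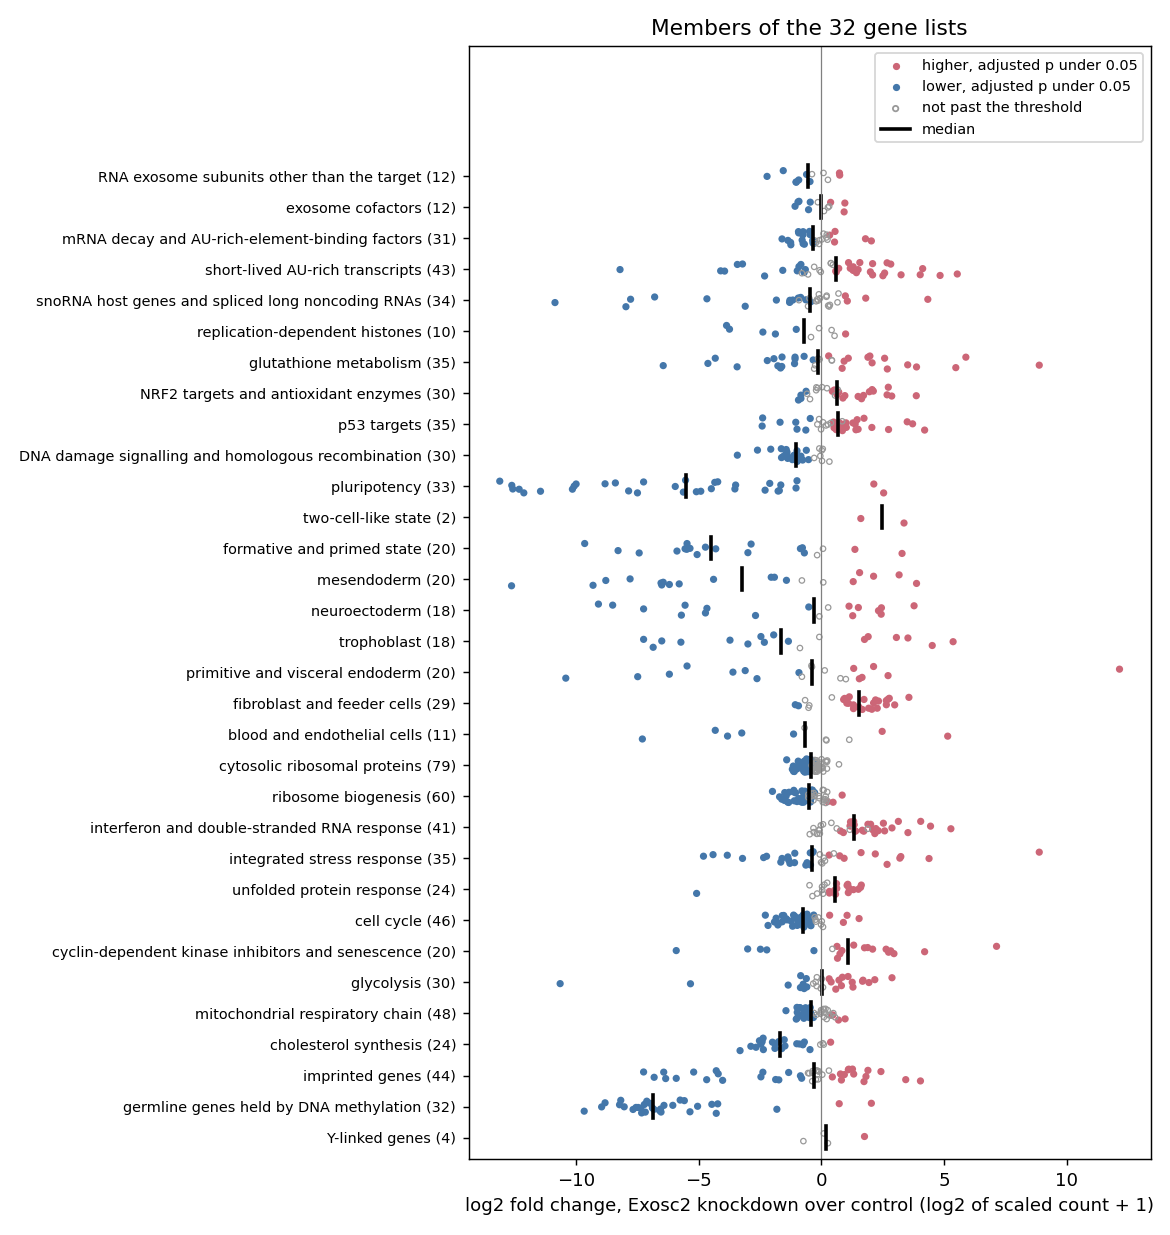
Log2 fold changes (knockdown over control) of the tested members of 32 gene lists, with the number tested in parentheses, filled points for members past an adjusted p of 0.05 and vertical bars for medians. The pluripotency and germline medians lie at -5.53 and -6.85, and the fibroblast and interferon medians at 1.53 and 1.32.

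Across the lists, camera with its preset correlation called 15 of 31, 6 higher and 9 lower, and none with an estimated correlation, where 3 had an unadjusted p under 0.05. The 9 other splits of the libraries into 3 and 3 also had 9 to 15 lists called at the preset correlation, with 0 changed genes in limma. Each of these mixed controls and clones unevenly, so part of the group difference remained, and such counts do not show what no difference gives. Counts adjusted over the list alone were identical to those given, except for 21 p53 targets that rose, 38 ribosome biogenesis genes that fell and 36 cell cycle genes that fell. Of 678 Reactome sets, 152 were called, 50 higher and 102 lower. None held with an estimated correlation (smallest adjusted p = 0.896, 25 sets at an unadjusted p under 0.05), and the other splits had 6 to 291 sets called. The lowest adjusted p, 7.1e-05, was shared by activation of ATR in response to replication stress (33 of 37 genes fell), activation of the pre-replicative complex (27 of 29) and chromosome maintenance (48 of 60). Ligand-dependent caspase activation (14 of 15 genes rose, adjusted p = 0.00240) and syndecan interactions (19 of 24 rose, adjusted p = 0.00495) led the sets that were higher. Only 53 Reactome sets were called with edgeR statistics, which were tested with cameraPR.

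Expression also differed by chromosome, and alike in the 3 clones. Among 12374 genes with a mean of at least 50, the median log2 fold change was 0.03, but it was -0.54 on chromosome 1, -0.54 on chromosome 14 and -0.44 on chromosome 8. It was 0.50 on chromosome 19, 0.46 on chromosome 6 and 0.36 on chromosome 5. The chromosome medians of the clones differed from each other by at most 0.19, and those of the controls lay within 0.15 of the control mean. In 1000 shuffles of genes over chromosomes, the largest median deviation was 0.32. Chromosome 2, which carries Exosc2, had a median of 0.05, but the medians of bins along it ran from -0.29 to 0.82. These bin medians lay further apart than in shuffles of genes within the chromosome. The chromosome median therefore does not give the shift of the region around Exosc2. For chromosome centring the medians were taken over all tested genes, so they differ from those printed here. With each library's chromosome medians subtracted, 11033 genes changed, and 10053 of these had changed in the same direction without it.

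**Figure D4:**
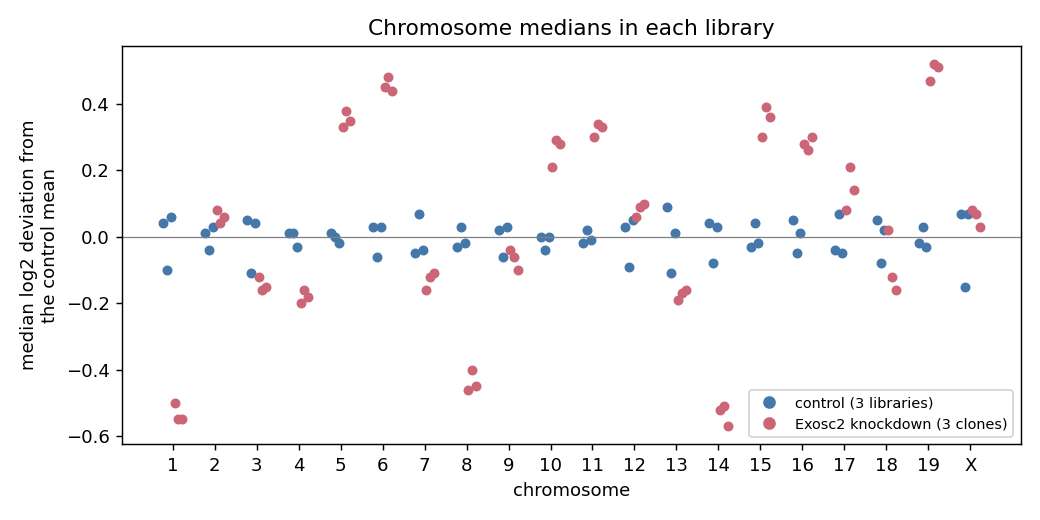
Median log2 deviation from the control mean of the genes on each chromosome, with a point for each of 3 control libraries and 3 Exosc2 knockdown clones. The clones lie together, near -0.5 on chromosomes 1 and 14 and near 0.5 on chromosomes 6 and 19, while the controls stay within 0.15 of zero.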

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

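Exosc2 kept its direction and its call under all alternatives run, with log2 fold changes from -1.34 with quantile normalization to -1.08 with chromosome centring, and from -1.25 to -1.08 when a sample was left out. The count of changed genes ranged from 9228 with a mean of at least 50 to 12553 without a filter, and from 10216 to 11379 when a sample was left out. Genes changed at least 2-fold ranged from 5471 to 8736, and from 7030 to 7354 when a sample was left out. The count of gene lists ranged from 13 to 16 in these settings, but 0 lists were called by camera with an estimated correlation (3 at an unadjusted p under 0.05). The count of Reactome sets fell to 53 with edgeR statistics, and the cause was not tested. It ranged from 126 to 199 in the other settings and from 133 to 211 when a sample was left out, and the list count from 14 to 16. The difference for genes with the AU-rich motif stayed between 0.15 and 0.24 without a call. Of named genes other than Exosc2, 8 values lost and 1 gained a call under other settings, and 7 lost and 1 gained when a sample was left out, with none changing direction while called. Exosc4, Exosc3 and Exosc10, Hist1h1a, Ddx3y and Eif2s3y were the genes concerned. The respiratory chain list gained a call with a mean of at least 50, with quantile normalization and without control replicate 3, decay factors with quantile normalization, short-lived AU-rich transcripts without a filter, and glutathione metabolism with DESeq2. No paired analysis was possible because the groups share no replicate number. Simulated 1.5-fold changes were recovered in 15.2% of cases, a rate that does not carry over to the real comparison. Small changes may still be missed with 3 libraries per group.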

Other observations

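Tests of the Pou5f1 pattern and of other splits of the samples, and the shuffles of 20 Mb bins, were chosen after their results were seen, and the other tests of the chromosome pattern before. A first test of the share of stem cells, on the Pou5f1 log2 fold change of 2.14, and a second, on the spread of pluripotency genes still measured in the clones, were replaced after their values were seen, the second because its genes were kept by their level in the clones. A test for feeder cells, on the number of fibroblast and feeder markers that fell (2), decided nothing and was dropped as a pattern to weigh.

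Imprinted genes, expressed from a single parental copy, moved both ways, with 14 higher and 17 lower of 44 (median log2 fold change -0.29, camera adjusted p = 0.675). Peg13 and H13 rose by 4.04 and 2.43 on the log2 scale, while Slc38a4 fell from 8690 ± 2275 to 78.3 ± 29.3. Among snoRNA host genes and spliced long noncoding RNAs, 4 rose and 15 fell of 34 (median -0.46, adjusted p = 0.107). The ESC transcripts Platr10 and Platr4 were at least 643-fold and 86.0-fold lower and Lincenc1 fell from 1538 ± 185 to 6.28 ± 2.28. Of 10 replication-dependent histone genes, which are poorly captured by poly(A) selection, 5 fell and 1 rose (median -0.72, 0.31 with quantile normalization and 0.17 with a mean of at least 50, adjusted p = 0.528). Hist1h1b fell from 43.2 ± 27.1 to 1.62 ± 0.519 and Hist2h2be rose by 0.99 on the log2 scale.

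Chromosome-wide shifts were alike in the 3 clones, and removing a trend with transcript GC content left 93.25% of the SD of the 20 chromosome medians, which argues against that trend as their whole cause. Whole-chromosome copy differences are a candidate explanation: 95.12% of 20 Mb bins (39 of 41) on the 6 most shifted chromosomes lay on the side of their chromosome, against a median of 71.43% and at most 87.80% in 1000 shuffles of genes over chromosomes (109 of 137 bins on all chromosomes lay on the side of the other genes of theirs), and broadly expressed ribosomal and respiratory genes followed the median of their chromosome with a slope of 0.96 (95% interval 0.77 to 1.15). Against a uniform shift, bin medians ran from -0.79 to -0.04 on chromosome 8 and from 0.04 to 0.98 on chromosome 5, further apart than in shuffles within the chromosome, as on 3 of the 14 other chromosomes. Copy differences of parts of chromosomes and regional changes of expression therefore stay open. DNA copy number was not analysed here, so an effect of Exosc2 loss cannot be separated from that of a different karyotype, if there is one.

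Pou5f1, Klf4 and Myc were higher while 30 of the 30 pluripotency genes other than Pou5f1, Sox2 and Klf4 were lower, 9 of them with at most 3 reads in the clones. Fewer stem cells and more of every other cell type would raise markers that stem cells lack. Of 91 markers from 6 lists of other cell types that passed the test, 43 were lower (47.25%, exact 95% interval 36.69 to 58.00%). So were 11 of the 18 with a control mean under 50. The interval takes genes as independent, which they are not. Markers that fell include genes high in the controls, such as Apoe (control mean 13212) and Peg10 (10096). Loss of stem cells could lower these too, so the share cannot decide. Fibroblast and feeder markers rose in 23 cases and fell in 2. A smaller share of control-like stem cells could lower Sox2 and the 30 genes that fell. It would not by itself raise Pou5f1, Klf4 and Myc, which were 4.33-fold, 5.87-fold and 44.8-fold higher. These 3 values argue against such a smaller share as the whole cause. Replacement of stem cells by a single other cell type high in these 3 transcripts stays open. Expression of Pou5f1, Sox2, Klf4 and Myc from introduced copies, as in reprogramming, is a hypothesis that the gene totals leave open. The lowest of the 4, Sox2, stood at percentile 85.72 of tested genes in the clones. Such a level cannot decide, since Pou5f1, Sox2 and Klf4 had control means of 21045, 11834 and 2415. Unlike Pou5f1, Klf4 and Myc, Sox2 was lower than in the controls (log2 fold change -2.10 ± 0.21). Read positions that would separate introduced from native transcripts were not analysed here, and an effect of the Exosc2 knockdown itself stays open and untested.

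The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 11158 changed genes and 7300 changed at least 2-fold, against 0 in each of the other splits, so 1 split, the real one, gave as many in both cases. Every other split mixed controls and clones, which adds the group difference to the spread within groups. Low gene counts there could thus be foreseen and decide nothing. For the list tests at the preset correlation, 2 splits, the real one included, gave at least the real 15, and the others ranged from 9 to 15. For Reactome sets, 4 splits, the real one included, gave at least the real 152, and the others ranged from 6 to 291. Part of the group difference stays in each mixed split, since its sides hold unequal numbers of clones. The list and set counts of the other splits are therefore not counts without a group difference. Whether this accounts for the many sets called was not tested.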
